A study of Homo sapiens with 11 samples.

How the data were processed

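Chromatin immunoprecipitation followed by sequencing was carried out in Ishikawa cells, a human endometrial cancer cell line. Per the labels, cells received 100 nM dexamethasone (a synthetic ligand of the glucocorticoid receptor, GR), 10 nM estradiol (the ligand of the estrogen receptor, ER), both hormones together (called the combination here) or the vehicle DMSO. Per the labels, ER and GR were profiled after 1 h of treatment, and histone H3 acetylated at lysine 27 (H3K27ac, a mark of active promoters and enhancers) after 8 h. The treatment protocol text for the H3K27ac samples also gives 1 h, so the time follows the treatment label of each sample. The series lists 11 samples, of which 8 were analysed here as peak lists: ER with estradiol, ER with the combination, GR with dexamethasone, GR with the combination, and H3K27ac with vehicle, estradiol, dexamethasone and the combination. The vehicle ER, vehicle GR and control samples were not analysed here as lists. Each group holds 1 library, whether that library pools cultures is not stated in the sources used here, and no replicate spread can be given.

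Reads were aligned with Bowtie 1.1.2 to the hg19 genome and peaks were called with MACS2 2.1.0.20140616, per the submitters' processing notes. Per the file headers, each ChIP library was compared with a control library at a p cutoff of 1e-10, with narrow peaks, at most 1 tag per position, an effective genome size of 2.7 Gb, local background windows of 1000 and 10000 bp, and the larger library scaled towards the smaller. The control tag totals in the headers are equal within the ER lists, within the GR lists and within the H3K27ac lists, and differ between those kinds. Scaling therefore reduced both ER libraries to a control of 3479280 usable tags, reduced the dexamethasone GR library to 5735043 tags, and left the combination GR library at its own depth. It reduced the vehicle H3K27ac library to 14002417 tags and left the H3K27ac libraries of the hormone treatments at their own lower depth.

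The deposited positions (start, end, summit and width) are 1-based hg19 coordinates in bp, checked from the width of every peak. The deposited pileup is a signal, the fragment coverage at the summit after scaling, per the file headers. Peak significance was deposited by the authors as −log10 of the p-value and of the q-value. The fold enrichment is the authors' ratio of the summit pileup to the local control background. Which control library served each list is known only as far as the tag totals show, and the labels of the control sample name both an input and IgG, so the kind of control behind the fold enrichment is uncertain. These values are the authors' own. They were used to rank or describe peaks within a list, since scaling and depth differ between lists. The exception is a simulation in the closing section, which matched a share of the combination ER pileups to the median combination GR pileup.

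Lists were compared by overlap of at least 1 bp, in each direction. Each share of peaks carries an exact Clopper-Pearson 95% interval over peaks, which covers counting error only, since neighbouring peaks and tags are not independent replicates. No p-value was computed between conditions. Background overlap was measured with 1000 random placements of each interval on its own chromosome and, as an alternative, at random points inside H3K27ac regions. Strength classes within a list were cut by the authors' −log10 q. The H3K27ac lists were merged into union regions, joining overlapping or bookended peaks, and each region was scored as present or absent in each of the 4 lists. A region present with a treatment and absent from the vehicle list is called gained, and the reverse lost; both words describe calls in lists, not levels. Receptor sites were assigned to a region when they lay within 1 kb. The gained to lost ratio of receptor shares carries a 95% interval on the log scale.

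The main comparisons, their overlap rules and the following settings were fixed before the data were examined: summits within 100 bp, intervals within 1 kb, lists cut to their stronger 50%, lists cut to equal length, the strongest 25% of the first list, another merging distance, other distances to a receptor site, and a stricter presence rule. Added afterwards were the shares of hormone-specific receptor sites, the H3K27ac count without the dexamethasone list, the further breakdowns by strength, by presence pattern and by chromosome, the summit distances, the regions followed across treatments, the grouping of neighbouring sites, the widths of H3K27ac peaks, and the tests of explanations in the closing section. Sites named in the text follow a rule fixed at the same time: in each class of sites, the 5 with the highest −log10 q of the authors, named by coordinates. Gene names, promoter shares, motif shares and the gene lists fixed beforehand were not analysed here, because no hg19 genome or annotation was used here. The overlap code was tested on simulated lists built from the real ones, and 100% of simulated sites were classified correctly in every list. The merging code was tested on fully simulated lists with known presence patterns, which it recovered. The code that cuts lists by strength was not tested in this way. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.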

Results

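ER, GR and H3K27ac were mapped in Ishikawa cells to ask how the receptors share the genome when their hormones are given singly or together. ER was called at 3560 sites with estradiol and at 2382 with the combination. GR was called at 1815 sites with dexamethasone and at 1628 with the combination. H3K27ac peaks numbered 21120 with vehicle, 23888 with estradiol, 15192 with dexamethasone and 20873 with the combination. Usable tags numbered 8508828 (estradiol) and 7625049 (combination) for ER, and 6353466 (dexamethasone) and 5206574 (combination) for GR. For H3K27ac they numbered 18508574 with vehicle, 10852521 with estradiol, 9034395 with dexamethasone and 9657258 with the combination. Duplicate tags made up 12% to 14% of the receptor libraries and 18%, 19%, 33% and 22% of these H3K27ac libraries in the same order. There were no replicates, so every difference below compares single libraries, and the 95% intervals are over peaks.

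The strongest ER sites were present with and without dexamethasone, and the ER list was shorter with the combination. Of the 3560 estradiol ER sites, 2200 (61.8%, 60.2 to 63.4) overlapped a combination ER site, against at most 0.169% in any random placement. The share fell with site strength: it was 98.9% in the strongest 25% of the estradiol list, then 81.1%, 45.5% and 21.7% in each following 25%. In the other direction, 2190 of 2382 combination sites (91.9%, 90.8 to 93.0) were estradiol sites. The estradiol list alone held 1360 sites and the combination list alone held 192.

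The strongest estradiol ER sites, all called with the combination as well, were chromosome 12 4120816 to 4121183 (fold enrichment 63.1), chromosome 6 131228193 to 131228448 (57.8), chromosome X 67682193 to 67682398 (55.9), chromosome 16 50994523 to 50994824 (56.3) and chromosome 15 39960696 to 39960988 (54.9). All 5 carried a GR site with the combination and 0 carried one with dexamethasone alone. The strongest site of the estradiol list alone was chromosome 10 4750548 to 4750697, with a fold enrichment of 25.5. Among sites of the combination list alone, the strongest was chromosome 4 77484633 to 77484974 (34.0), which carried GR sites with dexamethasone and with the combination. With both lists cut to equal length, 80.3% of estradiol sites were found with the combination.

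The GR lists differed in both directions, each holding many sites the other lacked. Of 1815 dexamethasone GR sites, 1031 (56.8%, 54.5 to 59.1) were called with the combination, and of 1628 combination sites 1028 (63.1%, 60.7 to 65.5) were called with dexamethasone. The combination list alone held 600 sites and the dexamethasone list alone held 784. In the strongest 25% of each list, 96.0% of dexamethasone sites were found with the combination, and 79.4% of combination sites were found with dexamethasone.

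The strongest GR site of the whole combination list, chromosome 3 150562321 to 150562612 (fold enrichment 93.2), had no counterpart in the dexamethasone list. The next strongest combination-only sites were chromosome 6 6703957 to 6704287 (74.9), chromosome 2 11638644 to 11638971 (73.1), chromosome 9 132321100 to 132321354 (59.2) and chromosome 15 39960722 to 39960969 (62.5). All 5 lay on ER sites of both ER lists. The strongest dexamethasone sites also called with the combination included chromosome 4 23932516 to 23932997 (91.0), chromosome 6 30894572 to 30894828 (96.7) and chromosome 17 8057659 to 8057936 (70.3). Of the top 5 in that class, 0 lay on estradiol ER sites and 3 lay on combination ER sites. The strongest dexamethasone-only site was chromosome 1 59910882 to 59911028 (32.1), with no ER site in either list.

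**Figure D1:**
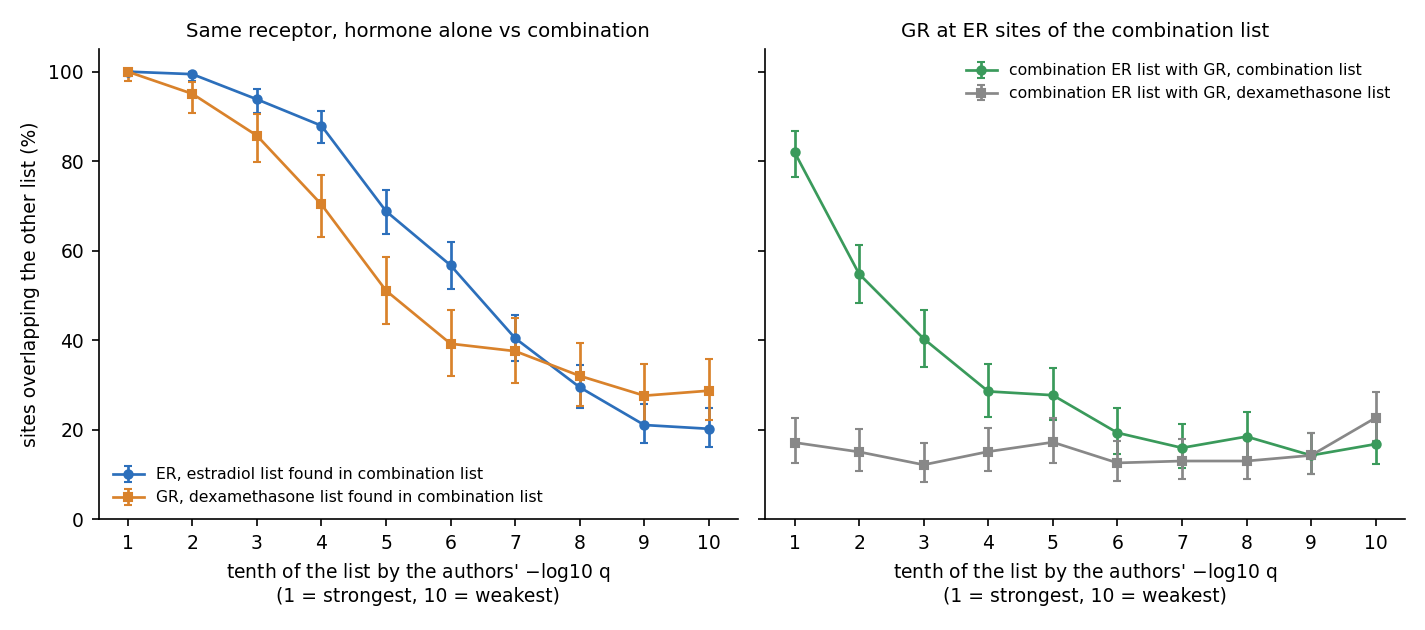
Share of sites overlapping another list (%, vertical axis) in steps of 10% of the list ranked on the authors' −log10 q (horizontal axis, 1 strongest to 10 weakest); points are shares and bars are 95% Clopper-Pearson intervals over sites. On the left, 100% of the strongest 10% of the estradiol ER list and of the dexamethasone GR list were found with the combination, falling to 20.2% and 28.7% in the weakest; on the right, GR of the combination list overlapped 82.0% of the strongest 10% of combination ER sites, while GR of the dexamethasone list overlapped 17.2%.

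GR was found at ER sites more often with both hormones than with dexamethasone alone, and the difference lay in the strong ER sites. Of the 3560 estradiol ER sites, 357 (10.0%, 9.06 to 11.1) carried a GR site with dexamethasone and 703 (19.7%, 18.5 to 21.1) carried one with the combination. In the strongest 25% of these ER sites the shares were 9.89% (8.01 to 12.0) and 42.6% (39.3 to 45.9). In the weakest 25% they were 11.8% (9.75 to 14.1) and 8.76% (6.99 to 10.8). Within the combination treatment, 759 of 2382 ER sites (31.9%, 30.0 to 33.8) carried a GR site. Where GR and ER sites of the combination overlapped, the median distance between their summits was 20 bp over 768 GR sites. Overlap of such narrow peaks (median widths 152 bp for GR and 197 bp for ER) itself keeps this distance short.

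Seen from the GR lists, 364 of 1815 dexamethasone sites (20.1%, 18.2 to 22) overlapped an estradiol ER site and 375 (20.7%, 18.8 to 22.6) overlapped a combination ER site. The order depended on strength: in the strongest 25% of dexamethasone GR sites, 14.3% (11.2 to 17.9) overlapped an estradiol ER site and 24.0% (20.1 to 28.2) a combination ER site, while in the weakest 25% the shares were 26.9% (22.9 to 31.3) and 21.2% (17.5 to 25.2), with overlapping intervals. Of the 1628 combination GR sites, 768 (47.2%, 44.7 to 49.6) overlapped a combination ER site. Random points inside H3K27ac regions gave a mean of 1.73% for this last overlap and at most 2.76%. The strongest GR sites of the combination list that coincided with ER of the same treatment were chromosome 3 150562321 to 150562612, chromosome 3 188665825 to 188666067, chromosome 3 127023005 to 127023397, chromosome 4 122990709 to 122990972 and chromosome 9 132195062 to 132195396. Of these, 4 were also GR sites with dexamethasone and 3 were ER sites with estradiol. With every list cut to its stronger 50%, 10.0% of dexamethasone GR sites overlapped estradiol ER sites and 39.7% of combination GR sites overlapped combination ER sites.

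The sites called for GR with the combination and not with dexamethasone were mostly ER sites. Of these 600 sites, 450 (75%, 71.3 to 78.4) overlapped an estradiol ER site, compared with 258 of 1028 GR sites shared by both treatments (25.1%, 22.5 to 27.9) and 107 of 784 dexamethasone-only sites (13.6%, 11.3 to 16.3). ER showed the mirror image on a smaller scale. Of the 192 combination-only ER sites, 81 (42.2%, 35.1 to 49.5) overlapped a dexamethasone GR site, compared with 282 of 2190 shared sites (12.9%, 11.5 to 14.4) and 76 of 1360 estradiol-only sites (5.59%, 4.43 to 6.94). Among GR sites that overlapped a combination ER site, the median summit distance was 17 bp at combination-only sites (463 sites) and 25 bp at shared sites (305 sites). At the 437 combination-only GR sites on ER sites of both lists, GR and ER strength of the combination lists rose together (Spearman rho 0.494, 0.407 to 0.569, across sites, which are not independent replicates). At the 305 shared sites rho was lower (0.309, 0.196 to 0.419), with overlapping intervals. Counting only combination-only ER sites of the stronger 50%, 71.4% overlapped a dexamethasone GR site, but these were 21 sites.

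**Figure D2:**
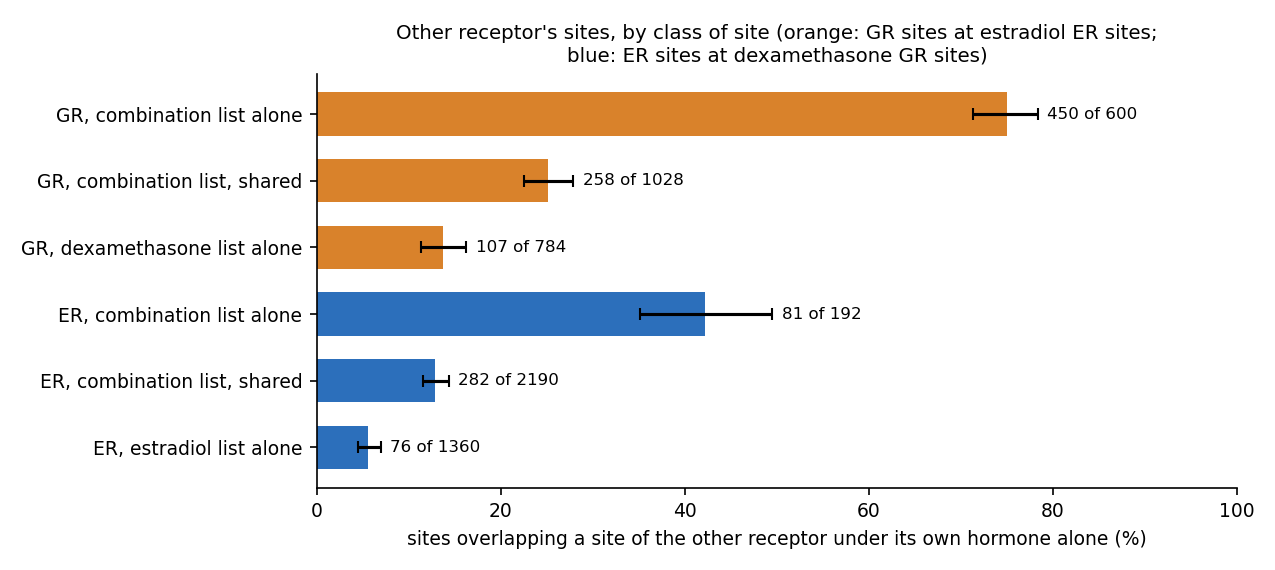
Share of sites (%, horizontal axis) that overlap a site of the other receptor called under its own hormone alone, for GR sites (orange) and ER sites (blue) by class; bars are shares with 95% Clopper-Pearson intervals and the numbers of sites beside them. Combination-only GR sites reach 75% and combination-only ER sites 42.2%, above the shared and hormone-alone classes of the same receptor.

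H3K27ac marked a minority of receptor sites with vehicle. ER and GR were mapped after 1 h and H3K27ac after 8 h, so here and below receptor binding at 8 h was not measured. It overlapped 1310 of 3560 estradiol ER sites (36.8%, 35.2 to 38.4) and 676 of 1815 dexamethasone GR sites (37.2%, 35.0 to 39.5) in the vehicle list. At the estradiol ER sites the share was 50.6% (49.0 to 52.3) in the estradiol H3K27ac list, 46.5% (44.8 to 48.1) with the combination and 27.5% (26.1 to 29.0) with dexamethasone. At the dexamethasone GR sites it was 36.9% (34.7 to 39.2) with dexamethasone, 43.9% (41.6 to 46.2) with the combination and 39.7% (37.5 to 42.0) with estradiol. Counting H3K27ac within 1 kb of these GR sites turned the order, with 52.8% for dexamethasone, 45.5% for vehicle, 48.0% for estradiol and 54.2% for the combination. Combination-only GR sites overlapped H3K27ac at 53.8% (49.8 to 57.9) with estradiol and 55% (50.9 to 59.0) with the combination, against 26.2% (22.7 to 29.9) with dexamethasone and 32.3% (28.6 to 36.2) with vehicle. Counting H3K27ac within 1 kb, these shares were 67.7%, 69.2%, 43.3% and 42.3%, so that dexamethasone no longer lay below vehicle. Dexamethasone-only GR sites overlapped H3K27ac at 43.5% (39.99 to 47.0) with estradiol, 43.0% (39.5 to 46.5) with the combination, 41.6% (38.1 to 45.1) with vehicle and 35.1% (31.7 to 38.5) with dexamethasone. Within 1 kb they lay between 51.1% and 54.0% in all 4 lists. The dexamethasone H3K27ac list was the shortest, and random placements of the ER sites met it at 0.523%, against 1.02% for the estradiol list. As an excess over random placement, dexamethasone GR sites met the dexamethasone list most, at 72.4 times. The combination list followed at 53.1, vehicle at 49.6 and estradiol at 40.5 times. At estradiol ER sites the excess was 52.7 (dexamethasone), 54.6 (combination), 47.5 (vehicle) and 49.5 times (estradiol).

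More H3K27ac regions were gained than lost with estradiol, and a minority of the gained ones had an ER site nearby, a larger share than among the lost ones. Of 27111 merged regions, 5919 were gained with estradiol and 1246 were lost. An estradiol ER site lay within 1 kb of 869 gained regions (14.7%, 13.8 to 15.6) and 36 lost regions (2.89%, 2.03 to 3.98), a ratio of 5.08 (3.66 to 7.05). Regions present in both lists had one at 8.70% (8.28 to 9.14). The strongest gained regions were chromosome 2 233237974 to 233242603, chromosome 15 39955608 to 39963017, chromosome 2 238465767 to 238469252, chromosome 16 9140550 to 9142672 and chromosome 11 69948532 to 69955798. All 5 carried ER sites in both ER lists and a GR site with the combination, 0 carried a GR site with dexamethasone, and all 5 were in the combination H3K27ac list. The strongest lost region was chromosome 9 74871054 to 74871956, and 0 of the 5 strongest lost regions had a receptor site within 1 kb. Gained regions were 82.6% of changed ones, and 66.0% with the lists cut to equal length, where estradiol gained 2928 regions, the combination 3199 and dexamethasone 4236. The stricter presence rule also left estradiol with the fewest gains (527, against 708 with dexamethasone and 848 with the combination). The ratio was 2.66 counting sites within 10 kb, 9.54 counting only sites inside the region, and 17.1 under the stricter presence rule, which left 1 of 35 lost regions with an ER site.

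After dexamethasone, 2940 regions were gained and 9568 were lost, and GR sites were rare at the lost ones. A dexamethasone GR site lay within 1 kb of 329 gained regions (11.2%, 10.1 to 12.4) and 72 lost regions (0.753%, 0.589 to 0.947), a ratio of 14.9 (11.6 to 19.1). Regions present in both lists had one at 8.87% (8.26 to 9.51). The strongest gained regions were chromosome 5 66563111 to 66565998, chromosome 13 83639342 to 83642768, chromosome 2 156065689 to 156067794, chromosome 6 35693696 to 35695879 and chromosome 13 83636832 to 83639278. Of these, 4 carried a dexamethasone GR site and all 5 were in the combination list. The strongest lost regions, chromosome 1 44411763 to 44413137, chromosome 16 1358579 to 1359749, chromosome 19 1652571 to 1653438, chromosome 19 1847892 to 1848903 and chromosome 13 113862501 to 113864727, had no receptor site and were present with estradiol and with the combination.

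The lost regions were not confined to weak vehicle peaks. The dexamethasone list contained 77.9% (76.8 to 79.0) of the strongest 25% of vehicle peaks, where the combination list, from a library of similar depth, contained 99.3% (99 to 99.5). Chromosome 19 held 5.86% of vehicle peaks and 4.08% of dexamethasone peaks, and chromosome 4 held 5.03% and 6.60%. Of the 9568 regions lost with dexamethasone, 5793 (60.5%, 59.6 to 61.5) were present with the combination. Gained regions were 23.5% of those that changed with dexamethasone and 40.3% with the lists cut to equal length, and the ratio of GR shares was then 28.2. It was 8.30 counting sites within 10 kb and 70.2 under the stricter presence rule.

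**Figure D3:**
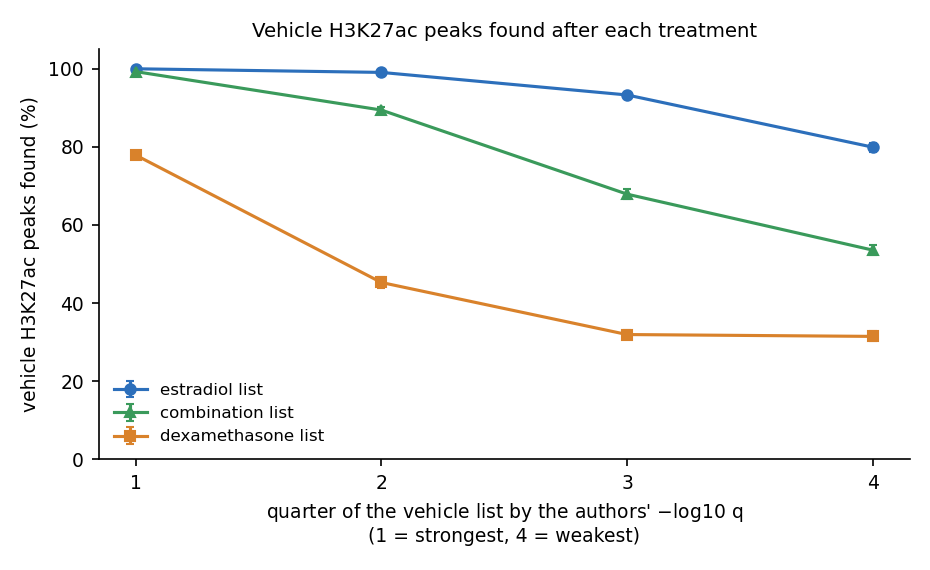
Share of vehicle H3K27ac peaks (%, vertical axis) that overlap a peak of each hormone treatment, in steps of 25% of the vehicle list ranked on the authors' −log10 q (horizontal axis, 1 strongest); points are shares with 95% Clopper-Pearson intervals, often smaller than the symbols. In the strongest 25% the shares are 100% for estradiol, 99.3% for the combination and 77.9% for dexamethasone, and in the weakest they are 79.9%, 53.6% and 31.5%.

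The combination list held part of the regions gained with each hormone. It contained 1942 of the 5919 estradiol-gained regions (32.8%, 31.6 to 34.0) and 1411 of the 2940 dexamethasone-gained regions (48.0%, 46.2 to 49.8). Against vehicle, it gained 4028 regions and lost 4081. The shared regions made up 48.2% (46.7 to 49.8) of its gains for estradiol and 35.0% (33.6 to 36.5) for dexamethasone. Regions found with estradiol and the combination and in no other list numbered 1447, and 474 of them (32.8%, 30.3 to 35.2) had an estradiol ER site within 1 kb while 29 (2.0%, 1.35 to 2.87) had a dexamethasone GR site. Regions found with dexamethasone and the combination and in no other list numbered 916, and 152 of them (16.6%, 14.2 to 19.2) had a dexamethasone GR site while 33 (3.60%, 2.49 to 5.02) had an estradiol ER site. Both shares were higher than in the regions seen with 1 hormone alone and not the combination. Of 3899 estradiol-only regions, 8.00% (7.17 to 8.90) had an ER site, and of 1451 dexamethasone-only regions, 7.72% (6.40 to 9.21) had a GR site. The regions shared with the combination were also wider, with medians of 645 against 353 bp (estradiol) and 591.5 against 304 bp (dexamethasone). Region width was not separated from presence with the combination. Under the stricter presence rule the combination gained 848 regions and lost 501, so gained regions made up 62.9% of the changed ones instead of 49.7%.

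H3K27ac regions of the combination list alone numbered 1170, beside 726 of the vehicle list alone, 1451 of the dexamethasone list alone and 3899 of the estradiol list alone. They carried sites of both receptors: 176 (15%, 13.0 to 17.2) had an estradiol ER site, 79 (6.75%, 5.38 to 8.34) a dexamethasone GR site and 104 (8.89%, 7.32 to 10.7) a combination GR site within 1 kb. Vehicle-only regions had an estradiol ER site at 1.24% (0.568 to 2.34) and a dexamethasone GR site at 1.93% (1.06 to 3.21). Regions in all 4 lists had them at 14.8% (14.0 to 15.6) and 9.07% (8.43 to 9.75), though they were wider (median 1562 against 344 bp). The combination-only share was thus alike for ER and lower for dexamethasone GR than in regions of all lists, with the GR intervals apart. The strongest combination-only regions were chromosome 10 73425594 to 73426617, chromosome 2 181588694 to 181589385, chromosome 3 117850302 to 117851233, chromosome 20 8326271 to 8328276 and chromosome 15 83587422 to 83588127. All 5 had ER sites in both ER lists and 4 had a combination GR site. Most were weak peaks: 59 of these regions remained when a peak in the stronger 50% of the combination list and none in the other lists was required, and leaving out the dexamethasone list raised the number to 2086.

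**Figure D4:**
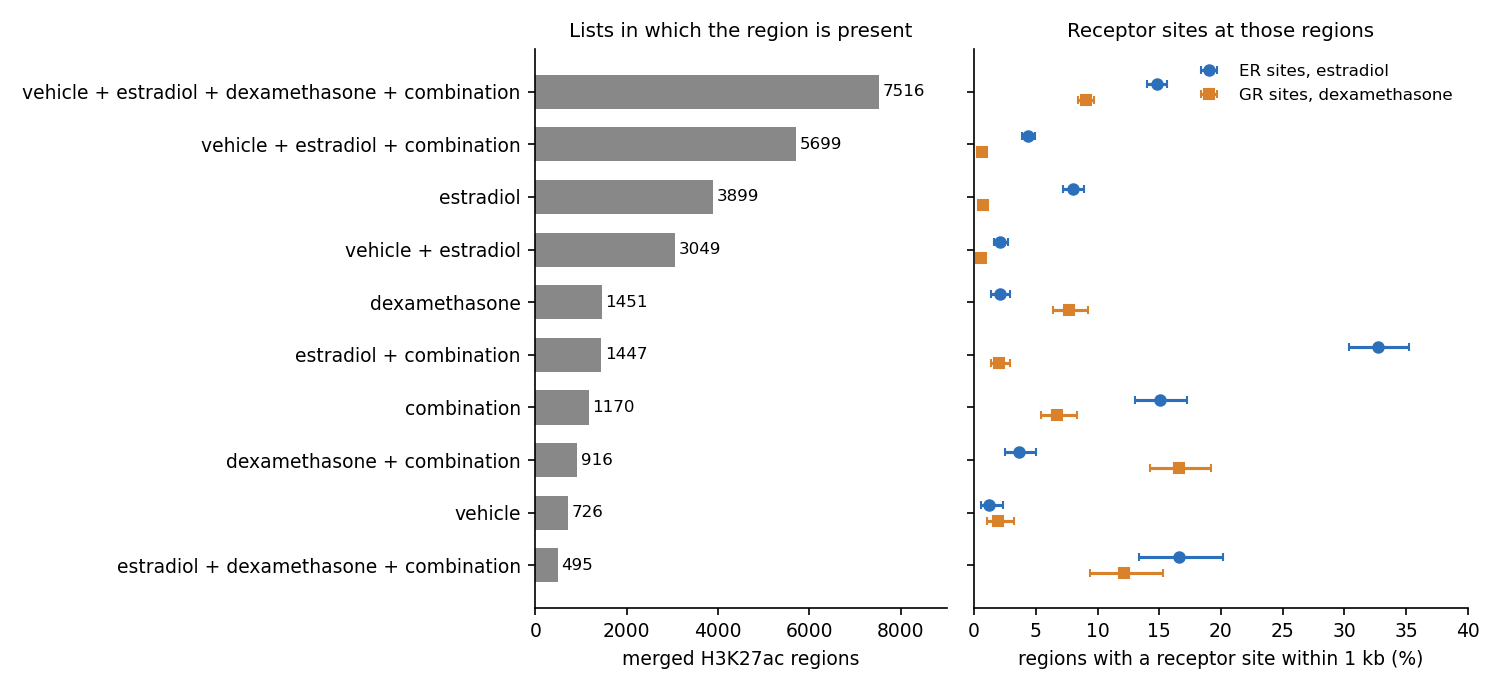
Number of merged H3K27ac regions by the lists in which they are present (left, the 10 most frequent of 15 patterns) and the share of those regions with an estradiol ER site (blue) or a dexamethasone GR site (orange) within 1 kb (right, %, with 95% Clopper-Pearson intervals). ER sites are most frequent at regions present with estradiol and the combination (32.8%), and GR sites at regions present with dexamethasone and the combination (16.6%).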

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

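Other settings moved most values beyond their limits (the counting interval, or 1.5 times for counts), while these orders held: GR was at a larger share of estradiol ER sites with the combination than with dexamethasone, and combination-only GR sites lay on ER sites more often than dexamethasone-only ones, under every setting run for both. The shares of hormone-specific receptor sites, with all their settings, and the count without the dexamethasone H3K27ac list were chosen after seeing the data. With summits within 100 bp, 90.3% of combination ER sites were found with estradiol, 8.46% of estradiol ER sites had dexamethasone GR, dexamethasone GR sites had ER at 16.5% (estradiol) and 17.1% (combination), and combination GR sites had combination ER at 43.8%. With intervals within 1 kb, 65.5% of estradiol ER and 59.4% of dexamethasone GR sites were found with the combination. Estradiol ER sites then had GR at 12.7% (dexamethasone) and 23.2% (combination), dexamethasone GR sites had ER at 23.6% (estradiol) and 23.5% (combination), and vehicle H3K27ac was at 45.7% of ER and 45.5% of GR sites. With every list cut to its stronger 50%, dexamethasone GR sites were found with the combination at 59.5% and the reverse at 66.2%. Estradiol ER sites then had GR at 5.17% (dexamethasone) and 15.4% (combination), dexamethasone GR sites had ER at 10.0% (estradiol) and 11.7% (combination), and combination GR sites had ER at 39.7%. Vehicle H3K27ac was then at 30.2% of ER and 27.7% of GR sites. Gained regions numbered 3014 (estradiol), 1754 (dexamethasone) and 2320 (combination), with 626 in the combination list alone. With lists cut to equal length, ER sites were found at 80.3% (estradiol list) and 80.2% (combination list), and GR sites at 60.0% (dexamethasone list) and 60.1% (combination list). Estradiol ER sites then had combination GR at 31.6%, dexamethasone GR sites had ER at 10.4% (estradiol) and 15% (combination), and combination GR sites had ER at 39.4%. Vehicle H3K27ac was then at 33.7% of ER and 34.9% of GR sites, 2928 regions were gained with estradiol and 4236 with dexamethasone, which turned the order of their gains (3199 with the combination), and the GR ratio of gained to lost regions was 28.2. In the strongest 25% of the first list, ER sites were found at 98.9% (estradiol list) and 99.5% (combination list), and GR sites at 96.0% (dexamethasone list) and 79.4% (combination list). Estradiol ER sites there had combination GR at 42.6%, dexamethasone GR sites had ER at 14.3% (estradiol) and 24.1% (combination), combination GR sites had ER at 52.6%, and vehicle H3K27ac was at 39.9% of ER and 31.6% of GR sites. Merging H3K27ac peaks within 1 kb gave 3131, 1260 and 2118 gained regions for estradiol, dexamethasone and the combination, and 488 in the combination list alone. Requiring a peak in the stronger 50% where present and none in the whole list where absent gave 527, 708, 848 and 59, again with fewest gains for estradiol, and gained to lost ratios of 17.1 for ER and 70.2 for GR. Those ratios were 9.54 and 10.9 for sites inside the region and 2.66 and 8.30 for sites within 10 kb. Without the dexamethasone H3K27ac list, 2086 regions were in the combination list alone. Hormone-specific sites of the stronger 50%, absent from the whole other list, lay on the other receptor's sites at 91.2% (GR, combination), 8.47% (GR, dexamethasone), 71.4% (ER, combination, 21 sites) and 2.25% (ER, estradiol). With all lists cut to their stronger 50%, these were 5.45% (GR, dexamethasone), 29.6% (ER, combination) and 2.75% (ER, estradiol), and with equal lengths 31.4% (ER, combination) and 3.84% (ER, estradiol). The values that stayed within their limits numbered 26, judged by the interval for shares and ratios and by 1.5 times for counts, so that the 4236 above is among them. Random points inside H3K27ac regions in place of whole chromosomes lowered the excess of the 9 receptor overlaps over chance from between 439 and 3192 times to between 8.94 and 66.5 times. Counts fell under stricter rules by construction; for the other shifts the cause was not tested. The planned promoter share, motif share and gene list results could not be run, because no hg19 genome or annotation was used here. No paired analysis was possible because each group has 1 library. A missing call is not a measured absence of binding. The depths were unequal, and no setting run here equalised them. Only the ER libraries had both been scaled to the same control total in peak calling.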

Other observations

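Groups of neighbouring receptor sites were counted along the genome, without a random expectation for their number, which also depends on list length. Joining sites at most 12.5 kb apart, the estradiol ER list formed 180 groups of 3 or more sites (18.7% of its sites), the combination ER list 82 (12.2%), and the dexamethasone and combination GR lists 48 each (8.87% and 10.3%). The largest estradiol group held 9 ER sites over 48.3 kb at chromosome 17 55952810 to 56001106. The largest groups of the other lists all fell on 1 segment of chromosome 11: 8 combination ER sites at 69042178 to 69069515, 6 dexamethasone GR sites at 69042086 to 69069389 and 7 combination GR sites at 69042188 to 69069492. These groups were chosen after their values were seen.

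Broad H3K27ac peaks were rich in receptor sites. In the widest 5% of estradiol H3K27ac peaks (1194 peaks of at least 2.87 kb), ER sites of the estradiol list occurred at 144 per Mb, against 52.6 per Mb in the other peaks, and combination GR sites at 60.7 against 18.6 per Mb. The excess was lower in the dexamethasone list, at 1.88 times for dexamethasone GR sites. The longest peaks of the estradiol and vehicle lists lacked receptor sites: the 28.7 kb estradiol peak at chromosome 1 82256378 to 82285082 held 0 receptor sites, and the same held for the 19.9 kb vehicle peak at chromosome 1 82262629 to 82282564. A 26.3 kb estradiol peak at chromosome 3 134071042 to 134097344 held 4 ER sites and 2 combination GR sites.

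Of the tests below, those on acetylated regions without ER and on rank agreement between receptors were set before their results were seen; all others, the pileup ranks and their simulation among them, were chosen after.

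Combination-only GR sites lay on ER sites, and weak calls near the threshold are argued against as the reason, since those in the stronger 50% of the list lay on estradiol ER sites at 91.2%, against 13.6% for dexamethasone-only sites. A higher background at acetylated chromatin was tested only away from ER sites. There, vehicle H3K27ac peaks carried GR less often with the combination than with dexamethasone (1.29% against 2.77%, ratio 0.465). The combination list was also shorter (1628 against 1815 sites). It held 920 GR sites off estradiol ER sites, against 1451 in the dexamethasone list. A ratio below 1 therefore follows in part from the pattern under test. No rise in calls was seen away from ER sites, but the ratio cannot decide on a general rise in background. Combination-only GR sites overlapped vehicle H3K27ac at 32.3%, below the 53.8% with estradiol. A raised background at ER sites or at chromatin acetylated with estradiol was therefore not tested. ER-bound material in the combination GR library, through the antibody or carry-over, cannot be told apart: GR and ER −log10 q ranked together with a Spearman rho of 0.494 (0.407 to 0.569) over 437 sites, below the 0.870 between the ER lists, the limit set beforehand. Pileups also ranked lower (0.691, 0.628 to 0.746, against 0.941). Noise lowers the rank agreement of carried-over material too, so that limit was too strict. Proportional carry-over was simulated with noise on the GR side only. It gave 0.790 (0.757 to 0.822) with counting noise, above the observed value. With the variance doubled it gave 0.668 (0.619 to 0.717), and the true noise is unknown. Recruitment of GR to ER-bound chromatin when both hormones are present may be offered only as a hypothesis beside that open one.

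The second pattern is the shorter ER list with the combination. Displacement of ER by GR at shared sites would lower the share found there. The opposite was seen with strength matched by steps of 25% of the list. Estradiol ER sites with a dexamethasone GR site were found with the combination at 78.7%, against 58.9% for those without (19.8 percentage points). In the strongest 25% nearly all were found either way (100% against 98.8%). Calls cannot show partial displacement. GR-bound material in the combination ER library could also raise the share and was not tested, so displacement is not excluded. Weaker sites falling under the cutoff would leave strong sites in place, and 98.9% of the strongest 25% were found. What placed the weaker sites under the cutoff was not measured, and an effect of dexamethasone and a difference between the libraries stay open with 1 library per group. Combination ER sites were fewest relative to estradiol ones on chromosomes 19 (ratio 0.508), 16 (0.524) and 22 (0.576). The dexamethasone to vehicle H3K27ac ratio was also lowest there (0.501, 0.430 and 0.533). Chromosome 17, denser in estradiol H3K27ac peaks than 16 or 22, was at 0.670 for ER. Fragment lengths in peak calling also differed (121 bp combination, 90 bp estradiol). Whether these differences bear on the shorter list was not tested.

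The third pattern is the loss of vehicle H3K27ac regions with dexamethasone. Lower depth alone is argued against, because the list lacked part of the strongest vehicle peaks (77.9% found) while the combination library of similar depth had 99.3%. Of these regions, 60.5% were present with the combination, which argues against a full loss there by dexamethasone with or without estradiol. Other values go the other way. With estradiol alone, 91.4% of these regions were present. Of all 17655 vehicle regions, 13574 were in the combination list, 16409 in the estradiol list and 8087 in the dexamethasone list. Regions lost with dexamethasone were thus in the combination list less often than vehicle regions as a whole, without matching for strength. Of the 4081 regions lost with the combination, 306 were in the dexamethasone list. A partial loss by dexamethasone when estradiol is present, or a loss at the remaining regions, is therefore not excluded. A composition bias of the dexamethasone library may contribute, and the library had 33% duplicates. Across 23 chromosomes the dexamethasone to vehicle peak ratio fell with the density of estradiol H3K27ac peaks (Spearman rho -0.537). Without the 2 chromosomes farthest from the median density, rho was -0.417. This trend cannot tell such a bias from an effect of dexamethasone. The combination to vehicle ratio showed the same trend (rho -0.582) over a narrower range, base composition was not analysed here, and an effect of dexamethasone that estradiol reverses stays open and untested.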
